A study of Mus musculus with 12 samples.

How the data were processed

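RNA of sorted mouse Treg was measured on 12 arrays, 3 for each of 4 groups that the labels name. The labels state that each population came from 3 experiments, with tumours pooled before the sort. Replicate numbers are those of the labels. Per the labels, total RNA was turned into biotin-labelled cRNA, whereas the file headers describe a scan in a single channel of an Agilent mouse expression array. Which of these describes the labelling was not settled. It bears on no value printed here because every array has 1 channel.

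The scanner files hold the deposited spot intensity of each array, made with Agilent Feature Extraction 9.5.3.1, per the file headers. Per the file headers, the processed intensity was background-subtracted and corrected for spatial and multiplicative trends within an array, with no normalization between arrays, and the probes were annotated on the mouse genome mm8 (NCBI build 36). The same files hold the mean intensity of each spot and the median intensity of its local background, per the file headers, which were used in 1 alternative. The series value table holds deposited values on a log10 scale, as their correlation with log10 of the processed intensity shows (Pearson r from 0.995 to 1.00 per array). Its columns have medians of 1.33 and are not centred per gene. The normalization behind them is not given in the sources used here. The value table served as an alternative only.

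Control spots were left out. Spots of 1 probe were averaged on the log2 scale, which reduced 43379 spots to 41174 probes. Probes were named through the RefSeq gene table of assembly GRCm38.p6, used for names only: 23374 by accession, 6733 by symbol and 2919 by synonym. Another 1244 kept the name in the file and 6904 had no gene name, for 20811 distinct genes. Probe coordinates are those of the files (mm8). No genome sequence was used here, so exons and untranslated regions were not analysed here. A gene was represented by its probe with the highest mean over the 12 arrays. Features entered the fit if their probe was well above background on at least 3 arrays, which left 15580 features, 12736 of them with a gene name.

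The level of a feature was log2 of the processed intensity minus the 75th percentile of that quantity on the array. All 12 arrays and 4 groups were fitted together with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with statmod 1.5.0 and the data.table package at version 1.17.8, so that the groups share 1 estimate of the spread per gene. The 4 contrasts were IL10+ against IL10- tumour Treg, total tumour against spleen Treg, and IL10+ and IL10- each against total tumour Treg. P-values were adjusted by Benjamini and Hochberg within a contrast, and a gene was called at an adjusted p under 0.05. The overlap of the calls of the first pair of contrasts was counted, and the genes higher or lower in tumour were tested with camera between the IL10 fractions. A planned Fisher's exact test of the overlap is not given, because both contrasts use 1 estimate of spread per gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

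The contrasts, their tests, the rule for named genes and the lists were chosen before the data were examined. Named genes were Il10, Foxp3, Il2ra and Tnfrsf1b in every contrast. Added were the 10 largest rises and 10 largest falls with a gene symbol in each of the first pair of contrasts, and 5 and 5 in the others, among called genes whose groups do not overlap, with predicted genes and clones left out. Also named were the 3 members with the smallest p of each programme list in the first pair of contrasts and the 2 brightest members of each cell type list. Of the genes that this rule names, 2 are not reported here. There were 17 programme lists (interferon-stimulated genes, Treg identity, effector Treg, suppressive mediators, resting lymphoid T cells, checkpoint and co-stimulatory receptors, Th1, Th17, Th2 and Tfh programmes, cell cycle, glycolysis and hypoxia, cholesterol biosynthesis, immediate early genes, heat shock and dissociation stress, NF-kB targets, and chemokine and homing receptors). There were 9 lists of other cell types (macrophages and monocytes, dendritic cells, neutrophils, B cells, plasma cells, CD8 T cells and NK cells, epithelial tumour cells, fibroblasts and endothelial cells, and erythroid cells and platelets). Some genes stand in more than 1 list. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists within a contrast. Alternatives were camera with the correlation estimated from the data and fry.

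The steps were tested on simulated data in which 200 of 15580 features were changed at each contrast, 67 by 1.5-fold, 67 by 2-fold and 66 by 4-fold. The share recovered at these folds was 8.96%, 31.3% and 74.2% for IL10+ against IL10- Treg, 1.49%, 31.3% and 62.1% for tumour against spleen, 8.96%, 26.9% and 68.2% for IL10+ against total tumour and 2.99%, 23.9% and 63.6% for IL10- against total tumour Treg. The simulated fits called 4, 2, 6 and 4 unchanged features in the same order. Noise was drawn independently for each feature and without slide or scan effects. Far fewer features were changed than were called between tumour and spleen, so these shares need not hold for the real arrays. The number of arrays limits the precision.

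Slide and scan were read from the file headers. One slide held IL10- replicates 1 to 3 and IL10+ replicate 2, another IL10+ replicate 3 alone. A further slide held IL10+ replicate 1 with total tumour replicates 1 and 2, and the last total tumour replicate 3 with the 3 spleen arrays. The first pair of slides shared 1 scan and the second pair another. Arrays of 1 group had no identical values (0% of probes). Alternatives were background correction by normexp with an offset of 50, quantile normalization, centring on the array median, no filter on dim probes, a filter that asks for signal above background on all 12 arrays, and the mean over the probes of a gene. Others were fitting only the 6 arrays compared, eBayes with trend and robust options, the series value table, a 2-fold minimum, slide or replicate number as a block, and leaving out each array in turn. Slide as a block for lists and named genes, the fit of only 6 arrays for named genes, scan as a block, lists without Il10, an estimated correlation without spleen replicate 2, leaving out both VERT-X arrays numbered 1, leaving out spleen replicate 2 in contrasts that do not use it, and a replicate block with only the 6 arrays compared were added after the data had been seen. Overlaps between contrasts that share arrays were set against 20 simulations of unchanged groups.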

Results

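Gene expression was measured in regulatory T cells (Treg), the CD4 T cells that restrain immune responses and are defined by the transcription factor Foxp3, sorted from subcutaneous MC38 tumours and from spleens of mice. MC38 is a mouse colon carcinoma line that grows in mice of its own strain. The 12 one-colour arrays fell into 4 groups of 3. Tumour Treg of VERT-X mice, whose Il10 gene drives a fluorescent reporter, were sorted as IL10+ or IL10-. The other groups were total tumour Treg of FoxP3-EGFP mice, whose reporter marks Foxp3, and spleen Treg of tumour-free FoxP3-EGFP mice. All cells were gated as CD45+, CD11b-low, CD3+ and CD4+, a gate that would remove macrophages, fibroblasts and B cells. A second gate was set on EGFP in FoxP3-EGFP mice or on CD25 (encoded by Il2ra) and CD120b (encoded by Tnfrsf1b) in VERT-X mice. Between 42.2% (IL10+ replicate 3) and 65.5% (IL10- replicate 1) of 41174 probes lay well above background. The 75th percentile of the processed signal ranged from 98.9 (IL10+ replicate 3) to 645 (IL10+ replicate 1). Pearson correlations across genes between arrays of 1 group were 0.987 to 0.989 in total tumour Treg, 0.964 to 0.982 in spleen Treg, 0.957 to 0.977 in IL10- and 0.927 to 0.957 in IL10+ tumour Treg. Levels below are log2 signal relative to the 75th percentile of the array, and differences are on the same log2 scale. In each comparison 15580 features were tested.

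The first comparison, of IL10+ with IL10- tumour Treg, asked what sets apart the tumour Treg that express interleukin-10. The Il10 probe (mm8, chromosome 1, 132851912 to 132851971) read 4.59 ± 0.89 (SD, n = 3) in the IL10+ and -0.04 ± 0.45 (SD, n = 3) in the IL10- fraction, with every IL10+ array above every IL10- array. This difference of 4.63 ± 1.01 (SE) did not pass limma's test over all genes (adjusted p = 0.345). It did without spleen replicate 2, an array that enters only through the shared estimate of spread (adjusted p = 0.0104, against 0.0104 to 0.981 over all alternatives). The other genes behind the sorts were at like levels in both fractions, with differences of -0.32 for Foxp3, -0.43 for Il2ra and 0.01 for Tnfrsf1b, none of which passed. Markers of cells outside the gate were bright in both fractions. The macrophage marker Apoe read 7.20 to 8.54 and the fibroblast marker Dcn 5.22 to 6.78. Here too, changes within Treg thus cannot be told apart from RNA of other cells in the sorted samples.

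**Figure D1:**
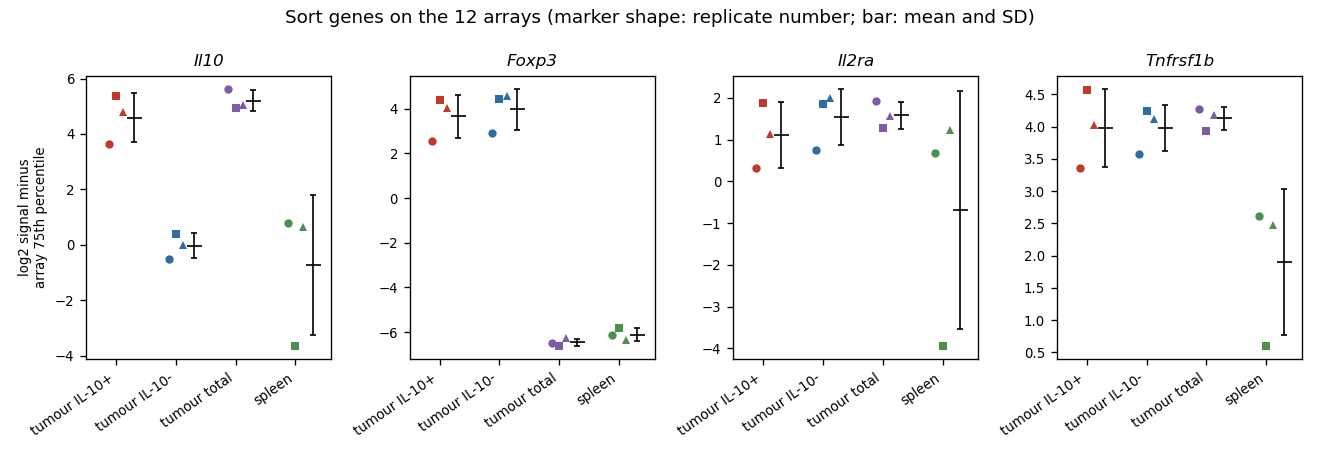
Log2 signal minus the 75th percentile of the array (y axis) of Il10, Foxp3, Il2ra and Tnfrsf1b on the 12 arrays by group (x axis). Marker shape gives the replicate number and bars the mean and SD (n = 3). Il10 averaged 4.59 in IL10+, -0.04 in IL10-, 5.20 in total tumour and -0.74 in spleen Treg, while Foxp3 averaged 3.65 and 3.97 in the VERT-X groups and -6.46 and -6.11 in the FoxP3-EGFP groups.

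Btla, Tnfrsf25 and Il18r1, receptors on lymphocytes, were lower in IL10+ than in IL10- tumour Treg. Btla, an inhibitory receptor of lymphocytes, fell by 1.86 ± 0.16 (SE) on the log2 scale (adjusted p = 0.00663). Tnfrsf25, a co-stimulatory receptor of the TNF receptor family, fell by 2.04 ± 0.21 (adjusted p = 0.0112) and Il18r1, a chain of the interleukin-18 receptor, fell by 1.84 ± 0.21 (adjusted p = 0.0147). In all, 8 genes passed at an adjusted p under 0.05, 1 higher and 7 lower, each by at least 2-fold. Over the alternatives the difference of Btla ran from -2.13 to -0.07, the smallest with normexp background correction (adjusted p = 0.916), where of the 8 genes only Tnfrsf25 (-1.95) and Il18r1 (-1.96) still passed. Csta2, of the stefin family of cysteine protease inhibitors, rose by 2.40 ± 0.28 (adjusted p = 0.0186). The hair keratins Krt86 (-2.41 ± 0.23, adjusted p = 0.00946) and Krt87 (-2.42 ± 0.27, adjusted p = 0.0147) fell, as did Actn2, an actin cross-linker of muscle (-1.52 ± 0.19, adjusted p = 0.0262). With normexp Actn2 changed direction, to 0.29. Csta2, Krt86 and Krt87 have near-identical family members, so which copy was measured is uncertain. Prm2, a protamine of sperm chromatin, fell too (adjusted p = 0.0401). It was not well above background in IL10+ Treg and was at least 13.4-fold lower there. Such bounds set the mean of the brighter group against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the signal of the probe itself.

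Several genes with large differences did not pass. They were the chemokine receptors Ccr6 (-4.59, adjusted p = 0.129) and Ccr7 (-2.18, adjusted p = 0.138), the inhibitory receptor Lag3 (3.0, adjusted p = 0.410), and Il18rap, the partner chain of Il18r1 (-1.72, adjusted p = 0.0989). The same held for Calca, which encodes calcitonin and a neuropeptide (2.39, adjusted p = 0.136), the transcription factor Stat4 (-1.04, adjusted p = 0.281) and the co-stimulatory receptor Cd226 (-1.54, adjusted p = 0.410). Without spleen replicate 2, 20 genes passed, among them the same 8, and Il10, Ccr6 (adjusted p = 0.0352), Ccr7 (0.0318) and Il18rap (0.0422) joined them.

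**Figure D2:**
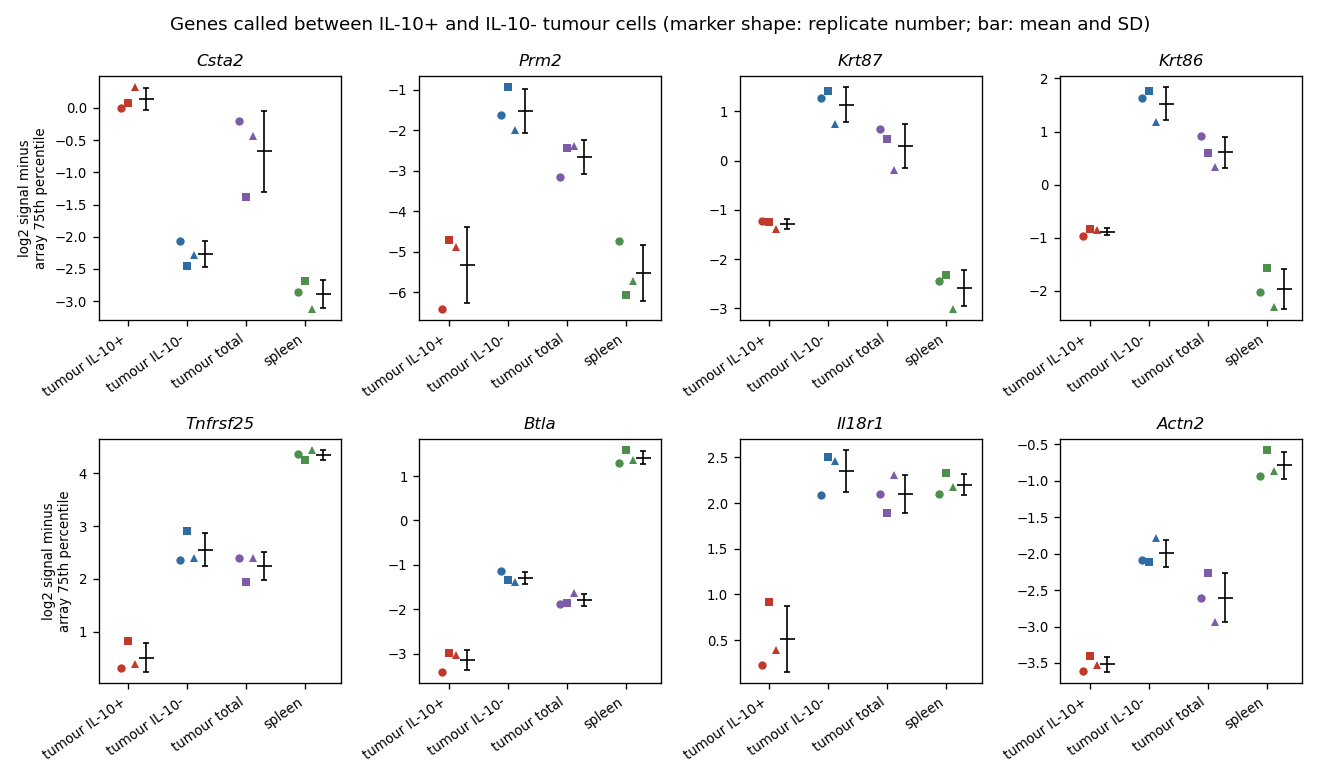
Log2 signal minus the 75th percentile of the array (y axis) of the 8 genes that passed between IL10+ and IL10- tumour Treg, on the 12 arrays by group (x axis); marker shape gives the replicate number and bars the mean and SD (n = 3). Csta2 was 2.40 higher in IL10+ Treg, 6 others differed by -1.52 (Actn2) to -2.42 (Krt87), and Prm2, not well above background in IL10+ Treg, was at least 13.4-fold lower.

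Of 26 lists of genes, 4 shifted between the IL10 fractions by camera, and none did once the correlation within a list was estimated. Suppressive mediators were higher, with a median of 0.36 (adjusted p = 0.0218; adjusted p = 0.890 with an estimated correlation). With normexp background correction camera's direction for them turned down. The list holds Il10, on whose reporter the fractions were sorted, and without it the list was not called (median 0.31, adjusted p = 0.0844). Of 16 genes, 0 passed over all genes and 2 rose adjusted over the list alone (Il10 and Lag3). Genes of the Tfh programme, that of helper T cells of B cell follicles, were lower, with a median of -0.37 (adjusted p = 0.0251; adjusted p = 0.890 with an estimated correlation). Btla fell over all genes, and 3 of 9 fell adjusted over the list alone, with Cd200 at -1.03 and Slamf6 at -0.75 beside Btla. Cell cycle genes had a median of -0.14 (adjusted p = 0.0148; adjusted p = 0.890 with an estimated correlation), with the replication genes Mcm3 at -0.45 and Mcm4 at -0.39 and 0 of 28 passing by either adjustment. Macrophage and monocyte markers, of cells outside the gate, were higher beside these groups, with 17 of 17 positive and a median of 0.41 (adjusted p = 7.3e-05; adjusted p = 0.890 with an estimated correlation), and none passed singly. Their direction, too, turned down with normexp. The other 22 lists were not called. Treg identity genes had a median of -0.19 (adjusted p = 0.963), effector Treg genes -0.10 (adjusted p = 0.962) and interferon-stimulated genes -0.03 (adjusted p = 0.962). For the last pair camera's direction was up, against a negative median and mean. Adjusted over the list alone, 1 of 17 checkpoint and co-stimulatory receptors rose and 3 fell, and 1 of 15 Th1 genes rose and 3 fell. Over all genes only Btla of the former and Il18r1 of the latter fell. By the same adjustment over the list alone, 1 resting lymphoid gene, 1 Th17 gene, 2 homing receptors and 1 neutrophil marker fell, 1 Th2 gene rose and 1 fell, and none of these passed over all genes. Plasma cell markers had a median of -0.17 and a mean of -0.04, with camera's direction up, and neutrophil markers a median of 0.29 and a mean of -0.02.

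With slide as a block limma called 0 genes (664 at an unadjusted p under 0.05), the median SE of the 8 genes going from 0.221 to 0.323, and with only these 6 arrays in the fit 0 (450 unadjusted). With replicate number as a block 2 of the 8 genes passed, both lower in IL10+ Treg, and with that block and only these 6 arrays 0 did. Whether equal numbers in the 2 fractions mark a shared experiment stays open. On the 1 slide that held both fractions (1 IL10+ against 3 IL10- arrays) all 8 genes kept their direction at a median of 0.923 times the full difference, with Il10 at 5.42. The calls rest on these arrays too. As the groups of all 8 genes do not overlap, their direction on this slide was fixed and does not test the slide. The count of 8 became 0 without IL10- replicate 2 (426 unadjusted), 2 without IL10+ replicate 1, 4 without IL10- replicate 1, IL10- replicate 3 or IL10+ replicate 3, 5 without IL10+ replicate 2 and 20 without spleen replicate 2. Of 15580 features, 725 (4.65%) had an unadjusted p under 0.05, and the 2 groups did not overlap for 1167 (7.49%, against 10% by chance). Blocking on slide gave the list medians of the 1 slide that held both fractions, where IL10+ replicate 2 alone stands for IL10+ Treg. Among the 4 called lists they were 0.48 for suppressive mediators, -0.33 for the cell cycle, -0.20 for Tfh genes and 0.14 for macrophage markers. Interferon-stimulated genes stood at 0.32 and effector Treg genes at 0.31. With 1 IL10+ array these medians do not test whether the calls withstand an effect of slide. None of the 4 lists kept its call without IL10+ replicate 3 or without IL10- replicate 1. The suppressive (adjusted p = 0.201) and cell cycle calls (0.237) were lost without IL10+ replicate 2. In addition 7 lists were called without IL10+ replicate 1, IL10- replicate 2 or spleen replicate 2.

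The second comparison set total tumour Treg against spleen Treg, both sorted on the Foxp3 reporter, and asked how Treg in a tumour differ from Treg in a lymphoid organ. By camera, genes of effector Treg, suppressive mediators, the cell cycle and glycolysis were higher in tumour Treg and genes of resting lymphoid T cells lower, and of these only glycolysis passed with an estimated correlation. Markers of fibroblasts and macrophages, higher, and of B cells, lower, moved beside them. The arrays read the RNA of whole sorted samples, so changes within Treg cannot be told apart from RNA of other cells. Il10 read 5.20 ± 0.38 (SD, n = 3) in tumour and -0.74 ± 2.53 (SD, n = 3) in spleen Treg. It rose by 5.94 ± 1.01 (SE, adjusted p = 0.00124), or by 4.48 (adjusted p = 1.90e-04) without spleen replicate 2, the array in which Il10 was lowest. Tnfrsf1b rose by 2.23 ± 0.50 (adjusted p = 0.00560; 1.58 without spleen replicate 2), while Il2ra, at 2.27 ± 1.12 (adjusted p = 0.129), did not pass. It stood at 0.64 (adjusted p = 0.357) without that array and passed without spleen replicate 3 (3.22, adjusted p = 0.0496). In a limma fit of all probes, another Il2ra probe passed (2.25, adjusted p = 0.0345), and those at 1.69 and 2.52 did not. The Foxp3 probe (mm8, chromosome X, 6751991 to 6752050) was not well above background on any of these 6 arrays. In all 6687 features passed, 3210 higher and 3477 lower in tumour, of which 2369 and 1877 changed by at least 2-fold. The groups did not overlap for 10336 of 15580 features (66.3%, against 10% by chance).

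The largest rise among named genes was that of Mela, a sequence of retroviral origin expressed in mouse tumours, which rose by 12.64 (at least 5879-fold, adjusted p = 8.1e-08). The monocyte-attracting chemokine Ccl2 rose by 9.98 (at least 996-fold), its relative Ccl7 by 9.30 (at least 469-fold) and Trem2, a receptor of macrophages, by 9.21 (at least 454-fold). The collagen genes Col6a1 and Col3a1 rose by 9.96 and 9.19, and Dcn, a proteoglycan of connective tissue, rose by 9.43. Without spleen replicate 2 they rose by 10.9, 10.91 and 10.23. Other probes gave smaller rises for Col3a1 (2.70) and for Dcn (1.38, which did not pass). The 10 largest falls were all in immunoglobulin genes, among them Jchain, which joins antibody subunits, at -11.45 (at least 2677-fold, adjusted p = 5.7e-05), a light chain segment of the Igkv4 family at -10.81 (at least 1744-fold) and the heavy chain segment Ighv1-9 at -10.10 (at least 1096-fold). Immunoglobulin segments resemble each other, so the segment is uncertain.

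Counts of a list are over all genes, and equal those adjusted over the list alone unless both are given. Effector Treg genes rose in tumour, 16 of 22, with 0 falling and a median of 2.09 (adjusted p = 6.2e-06; adjusted p = 0.254 with an estimated correlation). Without spleen replicate 2, which was lower than the other spleen arrays for this list (median -1.17), 15 rose, with a median of 1.60. Ccr2, a chemokine receptor of cells that enter inflamed tissue, rose by 3.45 ± 0.42, and Cd44, an adhesion receptor of activated T cells, rose by 1.55 ± 0.18. Suppressive mediators rose in 11 of 16 (12 rose and 1 fell adjusted over the list alone), with a median of 2.48 (adjusted p = 9.0e-05; adjusted p = 0.254 with an estimated correlation). Spleen replicate 2 was lower for this list too (median -1.28), and without it the median was 1.76, with 11 rising. Among them the cytotoxic protease Gzmb rose by 7.04 ± 0.76 (adjusted p = 8.5e-05; 5.94 without spleen replicate 2), the inhibitory receptor Havcr2 by 3.55 ± 0.20 (adjusted p = 2.5e-06) and the lectin Lgals1 by 2.20 ± 0.31. Treg identity genes rose in 7 and fell in 1 of 19 (6 and 1 adjusted over the list alone), with a median of 1.13 (adjusted p = 0.0428; adjusted p = 0.690 with an estimated correlation). The inhibitory receptor Ctla4 rose by 3.77 (adjusted p = 0.00717) and Entpd1, an enzyme that breaks down extracellular ATP, by 2.30 (adjusted p = 0.00806), or by 2.40 and 1.67 without spleen replicate 2, while Gpr83, a receptor typical of Treg, fell by 4.01 on the log2 scale (adjusted p = 0.00401). Without that array Gpr83 stood at -5.18. The median of this list was 0.32 (adjusted p = 0.411) without spleen replicate 2, and its call was also lost without total tumour replicate 1 (adjusted p = 0.0700) or replicate 3 (adjusted p = 0.0573).

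Resting lymphoid genes fell in 18 of 20 and rose in 1 (the same counts adjusted over the list alone), with a median of -2.26 (adjusted p = 2.0e-07; adjusted p = 0.249 with an estimated correlation). Tcf7, a transcription factor of naive and memory T cells, fell by 5.83 ± 0.40 on the log2 scale (adjusted p = 6.4e-06), Cxcr5, which guides lymphocytes to follicles, by 5.02 ± 0.35 and the quiescence factor Klf3 by 3.13 ± 0.25. The 1 rise was Ly6c1 (1.10), a surface protein, named after its value was seen. Tfh programme genes fell in 6 of 9 and rose in 2, Pdcd1 and Angptl2 (3.26), with a median of -1.69 (adjusted p = 0.0163; adjusted p = 0.254 with an estimated correlation). Checkpoint and co-stimulatory receptors went both ways, 8 rising and 3 falling of 17 with a median of 0.06 (adjusted p = 0.432), the falls including Btla (-3.21, adjusted p = 1.5e-06) and Cd160 (-4.35). Chemokine and homing receptors did so too, 7 rising and 6 falling of 22 (adjusted p = 0.892), with a median of -0.05 against a mean of 0.06. Th1 programme genes rose in 10 and fell in 1 of 15, with a median of 2.16 (adjusted p = 5.5e-04; adjusted p = 0.318 with an estimated correlation). The chemokines Ccl3 and Ccl4 rose by 6.59 and 5.44, and the fall was Stat4 (-1.06). Th17 genes rose in 4 of 12 (adjusted p = 0.0677, but 0.0428 without spleen replicate 1 and 0.0403 without spleen replicate 2). Among them Ltb4r1, a leukotriene receptor, stood at 3.53 and the transcription factor Maf at 1.76, or at 2.75 and 1.3 without spleen replicate 2. Th2 genes rose in 5 and fell in 1 of 11 (adjusted p = 0.0691, but 0.0428 without spleen replicate 1, 0.0374 without spleen replicate 3 and 0.0469 without total tumour replicate 2). Their median of 1.24 became 0.17 without spleen replicate 2, where 3 rose and 0 fell (adjusted p = 0.107). Among the genes were Calca at 8.12 (at least 228-fold), the growth factor Areg at 5.46 (3.88 without spleen replicate 2) and the chemokine receptor Ccr8 at 3.67 (adjusted p = 0.0181; 2.47, adjusted p = 0.0501, without spleen replicate 2, and 0.0538 without total tumour replicate 1). Another Calca probe stood at 3.51.

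Cell cycle genes rose in 26 of 28 (28 adjusted over the list alone), with a median of 1.47 (adjusted p = 1.6e-10; adjusted p = 0.254 with an estimated correlation). Spleen replicate 2 was lower for this list as well (median -1.01), and without it 26 rose, with a median of 1.14. The replication genes Mcm5 and Mcm3 rose by 1.40 and 1.14 and the tubulin regulator Stmn1 by 1.24. Glycolysis and hypoxia genes rose in 21 and fell in 1 of 24 (22 and 1 adjusted over the list alone), with a median of 1.77 (adjusted p = 6.1e-11). This was the 1 list of the 26 that still passed when the correlation was estimated (adjusted p = 0.0462 with an estimated correlation). Bnip3, a mitochondrial protein induced by hypoxia, rose by 3.87 ± 0.15 (adjusted p = 6.6e-07), and the glycolytic enzymes Tpi1 and Pgk1 by 2.88 ± 0.18 and 1.99 ± 0.12. The fall was Pdk1 (-1.23), a kinase that restrains the use of pyruvate within mitochondria, named after its value was seen. Cholesterol biosynthesis genes rose in 17 of 22, with a median of 0.91 (adjusted p = 1.6e-05; adjusted p = 0.254 with an estimated correlation). Without spleen replicate 2, 11 rose, with a median of 0.97. Among the genes were the sterol carrier Stard4 at 2.21 and Insig1, a sterol sensor, at 1.68. Heat shock and dissociation stress genes rose in 12 and fell in 1 of 17, with a median of 1.07 (adjusted p = 5.5e-04; adjusted p = 0.254 with an estimated correlation). The chaperones Hsp90aa1 and Hspd1 rose by 1.55 and 0.77. Immediate early genes rose in 10 and fell in 2 of 19 (11 and 2 adjusted over the list alone), with a median of 1.10 (adjusted p = 0.0111; adjusted p = 0.350 with an estimated correlation). Without spleen replicate 2, 5 rose and 2 fell, with a median of 0.85, and the list was still called. Ier3 rose by 6.35 (at least 81.5-fold) and Atf3 by 5.10. NF-kB targets rose in 6 and fell in 2 of 16 (adjusted p = 0.188), with Tnfrsf9, a co-stimulatory receptor, at 3.96 (2.85 without spleen replicate 2). Interferon-stimulated genes rose in 4 of 34 (3 adjusted over the list alone), with a median of 0.17 (adjusted p = 0.212) and Ifitm3 at 2.79 and Oasl2 at 1.23.

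Markers of cells outside the gate moved beside these groups. Fibroblast and endothelial markers rose in 9 and fell in 1 of 12 (median 5.22, adjusted p = 5.5e-04; adjusted p = 0.254 with an estimated correlation), with the matrix genes Dcn at 9.43 and Sparc at 5.39. Macrophage and monocyte markers rose in 14 of 17 (15 adjusted over the list alone; median 1.96, adjusted p = 1.1e-06; adjusted p = 0.254 with an estimated correlation), with the lipoprotein gene Apoe at 2.98 and the protease Ctsb at 0.99. Neutrophil markers rose in 3 of 7 (4 adjusted over the list alone; median 1.92, adjusted p = 0.0306; adjusted p = 0.254 with an estimated correlation). All 11 B cell markers fell (median -5.91, adjusted p = 1.3e-08; adjusted p = 0.200 with an estimated correlation), with Cd79b at -3.80. So did 4 of 6 plasma cell markers (median -4.37, adjusted p = 0.0111; adjusted p = 0.254 with an estimated correlation) and 5 of 8 erythroid and platelet markers (median -6.82, adjusted p = 0.00396; adjusted p = 0.254 with an estimated correlation), the globins Hbb-bt and Hba-a1 by -8.73 and -8.29. Not called were markers of dendritic cells (1 rose and 3 fell of 12, median -0.61, adjusted p = 0.338), of CD8 T cells and NK cells (1 rose and 4 fell of 10, median -0.82, adjusted p = 0.187, but 0.0374 without spleen replicate 3) and of MC38 and other epithelial cells (2 rose of 3, median 0.94, adjusted p = 0.187). Of the last, the keratin Krt18 rose by 2.30 (adjusted p = 0.0306), or by 1.29 without spleen replicate 2 (adjusted p = 0.0492), and no longer passed without total tumour replicate 1 (0.102), replicate 2 (0.0529) or replicate 3 (0.0606). Only 3 of the 10 genes of the epithelial list were measured, so its test says little on RNA of tumour cells. Mela, in none of the lists, rose by 12.64, and which cells its RNA came from was not tested.

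**Figure D3:**
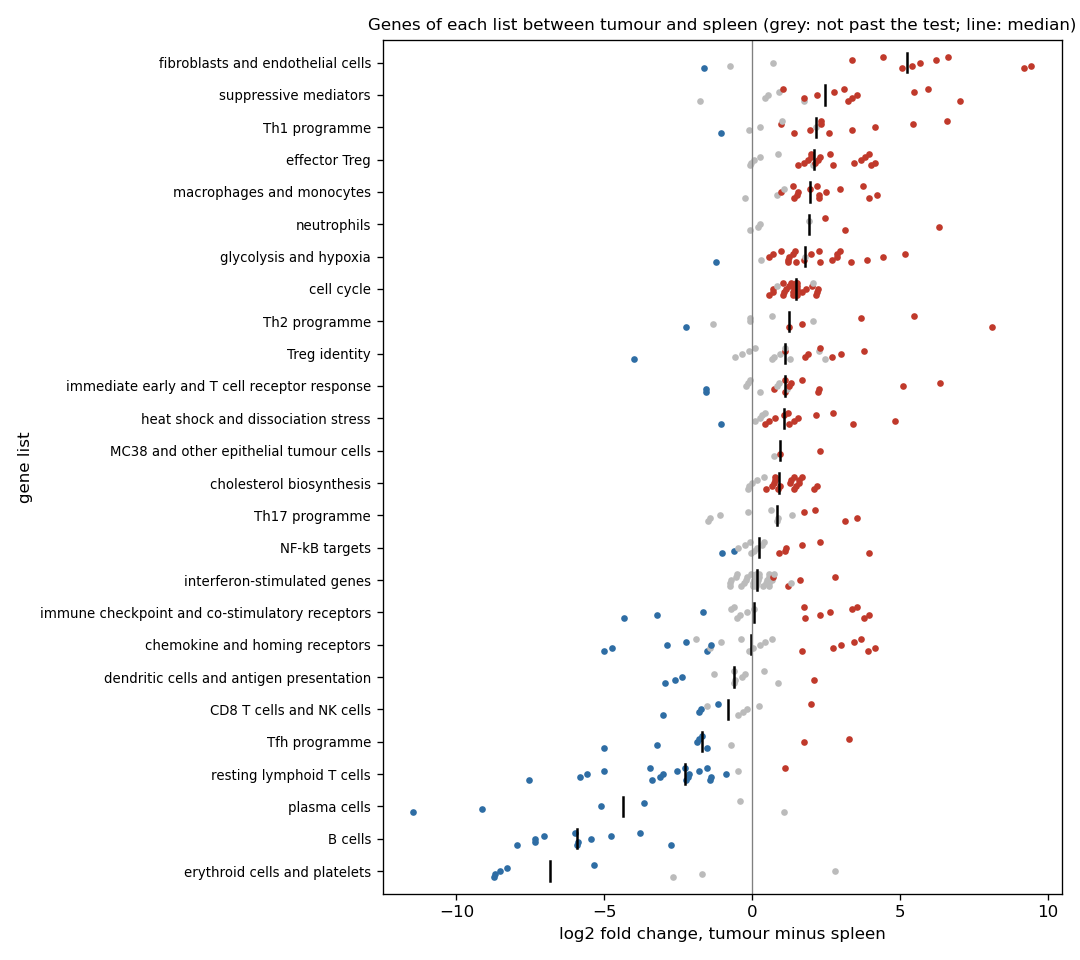
Log2 difference between total tumour and spleen Treg (x axis) of each measured gene of the 26 lists (y axis, 1 line per list). Red points rose, blue points fell, grey points did not pass, and the black line is the median. The medians ranged from -6.82 in erythroid and platelet markers to 5.22 in fibroblast and endothelial markers.

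With slide as a block 3464 genes passed, 1759 higher and 1705 lower, and Tnfrsf1b, Ctla4, Entpd1, Gpr83, Areg and Ccr8 no longer did (adjusted p from 0.0741 to 0.136). Nor did the lists of Treg identity (1.22, adjusted p = 0.0778), immediate early genes (0.88, adjusted p = 0.0757) and neutrophil markers (1.46, adjusted p = 0.0757). On the 1 slide that held both groups (1 tumour against 3 spleen arrays), 6686 of the 6687 genes and all 17 called lists kept their direction, at a median of 0.981 times the full difference. These arrays also gave the calls, so this is no independent test of slide. The slide block's list medians equal those on this slide, so its results rest on total tumour replicate 3 alone for tumour.

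Genes that differed between the IL10 fractions were then looked up in the tumour to spleen comparison, which compares other arrays but uses the same estimate of spread per gene. Of the 8 genes 7 also differed between tumour and spleen Treg, against 3.43 for independent lists. The shared estimate of spread favours the same genes in both comparisons, so no p is given for this count. Only 4 of the 7 went the same way. Csta2 was higher in both (2.40 and 2.21), and Btla (-1.86 and -3.21), Tnfrsf25 (-2.04 and -2.10) and Actn2 (-1.52 and -1.81) were lower in both. Krt86, Krt87 and Prm2 were lower in IL10+ Treg but higher in tumour Treg, Krt86 and Krt87 by 2.58 and 2.89 and Prm2, not well above background in spleen, at least 6.45-fold. Il18r1 stood at -0.10 between tumour and spleen. The 3210 genes higher in tumour had a median of 0.08 between the IL10 fractions (camera p = 8.6e-05; p = 0.248 with an estimated correlation), with 59.5% positive. The 3477 lower genes had a median of -0.08 (camera p = 0.00561; p = 0.318 with an estimated correlation), with 35.1% positive. Across all 15580 features, which are not independent replicates, the 2 sets of differences had a Pearson r of 0.239 and a Spearman rho of 0.218. The overlap was 0 without IL10- replicate 2, 2 without IL10+ replicate 1, 3 without IL10- replicate 1 or IL10+ replicate 3, 4 without IL10+ replicate 2 or IL10- replicate 3 and 16 without spleen replicate 2.

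IL10+ tumour Treg of VERT-X mice were next compared with total tumour Treg of FoxP3-EGFP mice. Strain and sort gate differ between these groups together with the IL10 fraction. The Foxp3 probe read 3.65 ± 0.97 (SD, n = 3) in the IL10+ fraction and -6.46 ± 0.17 (SD, n = 3) in total tumour Treg, where it was not well above background on any array, a difference of 10.11 ± 0.51 (SE, adjusted p = 2.1e-05; at least 1107-fold). Gdpd3, a phospholipid-cleaving enzyme, went the other way and fell by 7.42 ± 0.32 on the log2 scale (adjusted p = 9.9e-06). Il10 (-0.60, adjusted p = 0.788), Il2ra (-0.47) and Tnfrsf1b (-0.14) did not pass. In all 28 genes passed, 10 higher and 18 lower (2606 at an unadjusted p under 0.05; groups apart for 3540 features, 22.7% against 10% by chance). The collagen gene Col6a2 rose by 2.09 (adjusted p = 0.0463), Ttyh2, of a family of membrane channels, by 1.81 (adjusted p = 0.0229), the transcription factor Onecut2 by 1.74 (adjusted p = 0.0401) and Rbp2, a retinol carrier, by 1.57 (adjusted p = 0.0229). Another Col6a2 probe stood at 0.51 and did not pass. Falls were seen in the secreted factor Tafa3 (-2.03, adjusted p = 0.0256), the T cell receptor adaptor Trat1 (-1.85, adjusted p = 0.0367), Tnfrsf25 (-1.74, adjusted p = 0.0229) and Il18r1 (-1.59, adjusted p = 0.0254). With normexp Tafa3 changed direction, to 0.27. Btla, Il18r1, Krt86 and Tnfrsf25 were lower in IL10+ Treg against both IL10- and total tumour Treg, 4 shared calls against a mean of 0 in 20 simulations of unchanged groups and 0.00873 for independent lists. The simulated fits called at most 1 gene per comparison, so they had next to none to share and do not show what the shared arrays add. How much of this overlap comes from the IL10+ arrays and the estimate of spread that both comparisons use was not tested.

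By camera 6 lists shifted between IL10+ and total tumour Treg, each with adjusted p = 0.839 with an estimated correlation. Heat shock and dissociation stress genes were lower, with a median of -0.50 (adjusted p = 0.00234), 0 of 17 passing over all genes and 4 falling adjusted over the list alone, led by Hsp90aa1 at -0.89. Interferon-stimulated genes (-0.34, adjusted p = 0.0216; 2 of 34 fell adjusted over the list alone) and immediate early genes (-0.49, adjusted p = 0.0285) were lower as well. Higher were markers of macrophages and monocytes (0.44, adjusted p = 0.0216), of CD8 T cells and NK cells (0.59, adjusted p = 0.0484) and of erythroid cells and platelets (1.27, adjusted p = 0.0301), of which no member passed singly. With normexp background correction camera's direction for the macrophage list turned down. Treg identity genes were not called (adjusted p = 0.565), with a median of -0.15 against a mean of 0.36 that includes Foxp3. With slide as a block the list medians were those of the 1 slide that held both groups. IL10+ replicate 1 alone stands for its fraction there. That array stood apart from the other IL10+ arrays, as described below, so these medians cannot be read as those of the fraction. They were 0.15 for macrophage, 0.53 for CD8 and NK and 0.56 for erythroid markers. For interferon-stimulated genes, heat shock and immediate early genes they were -0.93, -0.90 and -0.51. The Th1 programme stood at -1.51, homing receptors at -0.99, NF-kB targets at -0.57 and glycolysis at 0.23. On the slide that held both groups (1 IL10+ against 2 total tumour arrays) all 28 genes kept their direction at a median of 0.983 times the full difference. The same arrays gave the calls, so this is no independent test of slide. With normexp background correction 1 gene passed, and with a replicate block 2 did. The count of 28 became 528 without IL10+ replicate 1 (all 28 among them, and no list called), 16 without IL10+ replicate 2, 9 without IL10+ replicate 3 and 2 without any 1 of the 3 total tumour arrays, and it was 39 without spleen replicate 2. Once IL10+ replicate 1 was left out no slide or scan held both groups. The 528 genes thus cannot be told apart from slide or scan effects. The 6 lists became 2 without IL10+ replicate 3 or total tumour replicate 3 and 3 without total tumour replicate 1.

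IL10- tumour Treg, too, differed most from total tumour Treg in Foxp3 and Gdpd3, under the same difference of strain and gate. Foxp3 was higher by 10.44 ± 0.51 (SE, adjusted p = 1.6e-05; at least 1384-fold) and Gdpd3 lower by -8.01 (adjusted p = 4.7e-06). Il10 stood at -5.24 ± 1.01 and did not pass (adjusted p = 0.0681), though it did without spleen replicate 2 (0.00373). Over the alternatives its adjusted p ran from 0.00373 to 0.518. Il2ra (-0.05) and Tnfrsf1b (-0.15) did not pass. In all 8 genes passed, 5 higher and 3 lower (2407 at an unadjusted p under 0.05; groups apart for 4340 features, 27.9% against 10% by chance). The RNA-binding protein gene Mex3d (1.27, adjusted p = 0.0404), the kinase-domain gene Dcakd (1.27, adjusted p = 0.0453) and Marcksl1, a regulator of actin (1.09, adjusted p = 0.0453), rose together with 1 predicted gene. Calca (-3.28, adjusted p = 0.0404) and Malt1, which links antigen receptors to NF-kB (-1.33, adjusted p = 0.0404), fell. Foxp3, Gdpd3, Mex3d and Dcakd also passed, in the same direction, for IL10+ Treg, 4 shared calls against a mean of 0 in 20 simulations of unchanged groups, which again called at most 1 gene per comparison, and 0.00668 for independent lists. How much of this overlap comes from the total tumour arrays and the estimate of spread that both comparisons use was not tested.

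Between IL10- and total tumour Treg 3 lists shifted by camera, each with adjusted p = 0.995 with an estimated correlation. Heat shock and dissociation stress genes were lower (median -0.62, adjusted p = 2.2e-04; 0 of 17 over all genes and 6 falling adjusted over the list alone, with Hsp90aa1 at -0.96), as were interferon-stimulated genes (-0.30, adjusted p = 0.0109; 3 falling adjusted over the list alone). Glycolysis and hypoxia genes were higher (0.26, adjusted p = 0.0113; 2 of 24 rising adjusted over the list alone). Treg identity genes had a median of -0.01 and a mean of 0.53 and were not called (adjusted p = 0.722). No slide or scan held both groups, and in a slide block fit that ties them through the other groups limma called 0 genes (1440 at an unadjusted p under 0.05) and 10 lists. The tie runs through IL10+ replicates 1 and 2, each the only IL10+ array on its slide. The count of 8 became 4 without IL10- replicate 1 or replicate 3, 2 without IL10- replicate 2, 2, 3 and 2 without total tumour replicates 1, 2 and 3, and 83, all 8 among them, without spleen replicate 2. Of the 83, 31 were higher and 52 lower. In turn 0 lists were called without IL10- replicate 1 and 6 without IL10- replicate 2.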

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

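The scan block, the lists without Il10, the estimated correlation without spleen replicate 2, the fits without both VERT-X arrays numbered 1, the 6-array fit with a replicate block, the slide block for lists and named genes, the 6-array fit for named genes and the fits without spleen replicate 2 of contrasts that do not use it were chosen after the data had been seen. Counts are given in the order IL10+ against IL10-, tumour against spleen, IL10+ against total and IL10- against total tumour Treg, where 8, 6687, 28 and 8 genes and 4, 17, 6 and 3 lists were called, and 7 genes overlapped between the first pair. Named genes stayed on the same side of the threshold in 3079 cases, lost the call in 262 and gained it in 13, and 2 called in 1 of the fits changed direction; for lists, by camera's direction, the numbers were 1420, 125, 56 and 11. Among those called in neither fit, the sign of the value differed for genes in 106 of 1803 cases and for lists, by the median, in 135 of 1115. Unless a cause is given, the cause was not tested.

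Normexp called 3, 1935, 1 and 3 genes, 9, 19, 10 and 5 lists, and an overlap of 2. Under it Btla shrank to -0.07 and Prm2 to -0.19 between the IL10 fractions, where Actn2 reversed to 0.29, and Tafa3 to 0.27 against total tumour Treg. Between the IL10 fractions it turned camera's direction from up to down for interferon-stimulated genes (median -0.75) and effector Treg genes (-1.21), whose medians were negative before, and for suppressive mediators (-0.26), heat shock (-1.12) and macrophage lists (-0.74). For IL10+ against total tumour it did so for glycolysis (-0.77) and macrophages (-0.57). Its offset of 50 is large beside a 75th percentile of 98.9 on IL10+ replicate 3, so by construction it compresses that array more than the others. Signal over background thus limits what this array can show.

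Quantile normalization called 16 genes (6 higher) and 3 lists for IL10+ and 18 genes (6 higher, 12 lower, against 5 and 3) for IL10- against total tumour. Centring on the array median called 1, 4010, 8 and 8 genes, with 0, 1 and 1 higher in the contrasts of VERT-X mice, and shifted the median difference by -0.41 for IL10+ and -0.38 for IL10- against total tumour. The series value table called 14 genes (6 higher) and 2 lists for IL10+ and 14 genes (5 higher, 9 lower) for IL10- against total tumour. Without a filter on dim probes, which tests 27715 features, the shifts were -0.30 for tumour against spleen and 0.32 and 0.24 for IL10+ and IL10- against total tumour. Then 2, 4901, 2 and 2 genes were called (1 higher and 1 lower in each of the last pair) and the overlap was 2. Probes above background on all 12 arrays gave 122 (22 higher) and 78 (18 higher) genes for the last pair, and trend and robust options 98 (23 higher) and 47 (15 higher). The mean of probes gave 2 for IL10- against total tumour. Asking for 2-fold left 4246 genes for tumour against spleen. With only the 6 arrays compared, 0 (450 unadjusted in limma), 2 and 3 genes were called in the contrasts of VERT-X mice and the overlap was 0, with fewer degrees of freedom by construction.

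With slide as a block 0 (664 unadjusted in limma), 3464, 3 and 0 (1440 unadjusted) genes were called, and 10 lists for IL10- against total tumour, where camera's direction changed for cholesterol biosynthesis (median 0.52), NF-kB targets (-0.51) and fibroblast markers (1.73), from medians near 0. With scan as a block 2, 9 and 4 genes were called in the contrasts of VERT-X mice. Both blocks tie VERT-X to total tumour arrays through IL10+ replicate 1, the only VERT-X array on a slide or scan with them. In the slide block, IL10+ replicate 2 alone stands for IL10+ between the fractions, and total tumour replicate 3 alone for tumour against spleen. With an estimated correlation 0, 1, 0 and 0 lists were called, and by fry 0, 19, 0 and 0. With spleen replicate 2 left out and an estimated correlation, 0 lists were called between the IL10 fractions. Taking Il10 out of the lists left 3, 6 and 3 in the contrasts of VERT-X mice, suppressive mediators between the IL10 fractions losing the call (0.31, adjusted p = 0.0844). Without both VERT-X arrays numbered 1, 0 genes were called between the IL10 fractions (1263 at an unadjusted p under 0.05 in limma) with an overlap of 0, but 1788 and 1271 against total tumour Treg, which kept the 28 and 8. In each of these 3 contrasts 0 lists were called. No VERT-X array that was left shared a slide or scan with a total tumour array. The 1788 and 1271 genes thus cannot be told apart from slide or scan effects.

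With a replicate block 2, 7892, 2 and 2 genes and 2, 17, 5 and 3 lists were called, and the overlap was 2. With only the 6 arrays compared and a replicate block, 0 genes were called between the IL10 fractions (1588 unadjusted) and 6991 between tumour and spleen. Deviations from the group means correlated by 0.41, 0.43 and -0.24 between IL10+ and IL10- arrays of the same number and by -0.02, 0.08 and -0.00 between tumour and spleen arrays. Not every array correlated best with its own number, so the main fit did not pair the samples. Between the IL10 fractions, though, arrays of the first 2 numbers did so, and only those of the last number did not. Whether equal numbers mark a shared experiment there stays open. If they do, the smaller gene counts with a replicate block apply to that comparison.

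Leaving out 1 array gave 0 to 20, 5098 to 5692, 2 to 528 and 2 to 83 genes, 0 to 7, 16 to 19, 0 to 6 and 0 to 6 lists, and an overlap of 0 to 16. The median of interferon-stimulated genes between the IL10 fractions ran from -0.34 (without IL10- replicate 1, where camera's direction turned down) to 0.15, against -0.03 with all arrays.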

Other observations

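The counts over other splits of the arrays were planned, and the tests of the arrays that stand apart and of the Foxp3 probe were chosen after the results had been seen. Homing receptors changed in both directions between tumour and spleen Treg, as genes picked after their values were seen show. Cx3cr1, the fractalkine receptor, rose by 3.92 (adjusted p = 7.38e-04 in limma), Cxcr6 by 2.72 and Ccr3 by 1.70. Ccr9, which guides T cells to the gut, fell by 4.74 on the log2 scale (adjusted p = 0.00363), the integrin chain Itga4 by 2.87 and S1pr1, needed to leave lymphoid organs, by 2.24. Among co-stimulatory receptors Icos rose by 2.28 and Tnfrsf4 by 2.65, and Cd226 fell by 1.67. Of the Tfh programme, the transcription factor Bcl6 fell by 1.69, the receptor Slamf6 by 1.87 and its adaptor Sh2d1a by 1.80.

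Without spleen replicate 2 in the shared estimate of spread, the genes lower in IL10+ than in IL10- tumour Treg also took in Scin, an actin-severing protein (-3.47, adjusted p = 0.0247), the phospholipase Pla2g4f (at least 13.0-fold lower, adjusted p = 0.0352), and the secreted trefoil peptide Tff1 (-2.70, adjusted p = 0.0139). The same held for the lipid enzyme Dgat2 (-1.90, adjusted p = 0.0208), the receptor partner Ramp3 (-1.48, adjusted p = 0.0414), Rnf32 (-1.71, adjusted p = 0.0487) and Tnp2, a sperm chromatin protein like Prm2 (-2.49, adjusted p = 0.0126). Lists of NF-kB targets (-0.22, adjusted p = 0.00797), glycolysis (-0.19, adjusted p = 0.0324) and markers of CD8 T cells and NK cells (0.44, adjusted p = 0.00797) were then called as well, but not with an estimated correlation (adjusted p = 0.712 for each).

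The array labelled spleen replicate 2 had Treg identity genes at a median of -2.81 against the other spleen arrays, lower for 18 of 19 genes, with Ikzf2 at -4.43, Il2ra at -4.90, Ctla4 at -4.10 and Il10 at -4.39, and the T cell cytokines Il4 and Il2 higher by 4.44 and 3.43. A dim array is argued against by the 75th percentile of its signal before centring, 317 against 325 and 397 on the other spleen arrays (-0.179 on the log2 scale), and dilution of Treg RNA by cells other than T cells by the median of 16 T cell genes, 0.30. Resting lymphoid T cell genes were higher by 0.60, in line with a sample that may hold T cells other than Treg, which stays open although the gate on EGFP would remove cells without Foxp3, as does a wrong label. Markers of fibroblasts (1.73), of CD8 T cells and NK cells (1.68) and of erythroid cells (1.51) were also higher on it, with no explanation tested for these. Leaving it out moved the calls between the IL10 fractions from 8 to 20 and those of IL10- against total tumour Treg from 8 to 83, although neither contrast uses it.

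The Foxp3 probe was well above background on 6 of 6 VERT-X arrays and on 0 of 6 FoxP3-EGFP arrays, though the latter were sorted on the Foxp3 reporter. A tumour sample without Treg is argued against by the other Treg identity genes, whose median differed by 0.0265 between total tumour and VERT-X tumour arrays, and slide or scan by the difference of 9.05 on the slide that holds both strains. A reporter allele that alters the transcript at the probe is a candidate explanation, with 0 FoxP3-EGFP arrays above background, and cannot be told apart from other differences between the strains for these 6 arrays, because the array carries 1 Foxp3 probe and the construct is not given in the sources used here. Gdpd3 was the reverse, at 4.36 to 5.95 on the FoxP3-EGFP and -3.68 to -2.56 on the VERT-X arrays.

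The VERT-X arrays numbered 1 stood apart from the others of their groups, with fibroblast and endothelial markers higher by 1.24 (IL10-) and 1.18 (IL10+), Dcn reaching 6.60 and 6.78 and Col1a1 2.43 and 3.1. Slide as the source is argued against by the 1.24 of the IL10- array, which was measured against IL10- arrays on its own slide. T cell genes were lower by a median of -0.77 and -1.05, as a larger share of stromal RNA could give, which stays open although the gate on CD45 and CD3 would remove fibroblasts, while macrophage markers stood at -0.39 and -0.05. A larger stromal share is argued against as the only cause of the differences in Cd3e (-3.53 and -3.60) and Cd4 (-2.27 and -2.84), which stood at -1.59 or lower beyond the other T cell genes. Cd3e read 1.97 and 1.64 on these arrays, 4.7 to 5.8 on the other VERT-X arrays and 2.5 to 3.4 on the FoxP3-EGFP arrays. Cd4 read 0.14 and -0.26, 2.1 to 2.7 and 0.3 to 1.4 in the same order. For both genes the other VERT-X arrays thus lay further from the FoxP3-EGFP arrays than those numbered 1. Without these 2 arrays, IL10+ and IL10- Treg differed from total tumour Treg in 1788 and 1271 genes and from each other in 0 (1263 at an unadjusted p under 0.05 in limma). Of the VERT-X arrays left, none shared a slide or scan with total tumour Treg. Slide or scan effects thus cannot be told apart from the differences of these 1788 and 1271 genes.

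IL10+ replicate 3, the dimmest array, had higher markers of B cells (1.76), plasma cells (2.02), erythroid cells (1.75) and neutrophils (1.20) than the other IL10+ arrays.

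With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Between the IL10 fractions 8 genes were called, and 3 of the 10 splits called as many, the highest other calling 721. That split sets IL10- replicate 1, IL10+ replicate 1 and IL10+ replicate 3 against the 3 other arrays, which lie on 1 slide. It points to a structure of the samples that does not follow slide alone, since IL10- replicate 1 lies on that slide too. With slide as a block 0 genes were called (664 at an unadjusted p under 0.05 in limma), with the median SE of the 8 genes going from 0.221 to 0.323. Their differences were then a median of 0.923 times the full ones. That is no independent test, since the same arrays gave the calls. For lists the real split called 4, 5 splits called as many and the highest other called 8. Between tumour and spleen the real split called 6687 genes, 1 split called as many and the highest other called 0. For lists it called 17, 3 splits called as many and the highest other called 18. For IL10+ against total tumour the real split called 28 genes, 1 split called as many and the highest other called 2. For lists the numbers were 6, 3 and 10. For IL10- against total tumour the real split called 8 genes, 1 split called as many and the highest other called 0. For lists the numbers were 3, 8 and 10.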
